A study of Mus musculus with 6 samples.

How the data were processed

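Liver RNA of 6 male mice aged 12 weeks, 3 chromogranin A knockout and 3 wild type, was measured on Affymetrix mouse arrays, 1 array per sample. Per the labels' protocols, total RNA was extracted with a guanidinium thiocyanate kit, treated with DNase and converted to biotinylated cRNA. Per the submitters' processing notes, the arrays were processed with GCOS 1.2, the Affymetrix operating software. The deposited values are linear probe set intensities in arbitrary units, with 1 column per array and no detection calls used here. The mean of the values left after trimming 2% at each end ran from 2501.32 to 2501.42 over the arrays, so each array had been scaled to a common level before deposit; the rule behind the scaling is not given in the sources used here. The labels name neither the genetic background of the wild-type mice nor feeding state, hour of dissection or array batch, and p-values measure only the spread between these samples.

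The table held 22690 probe sets, of which 64 control probe sets were left out. The platform annotation gave 20380 of the remaining 22626 probe sets 1 gene, 691 several genes, and 1555 none, and no gene was named from a probe set with several. Symbols were updated through the RefSeq gene table of assembly GRCm38.p6, which also gave the order of genes along chromosomes. The files name no genome build, so no coordinates are given. Probe sets in the upper 60% by mean log2 value were kept, 13576 in all, of which 12475 stood for 1 gene each and together for 8047 genes.

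Values were tested as log2(intensity + 16) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), all 6 arrays in 1 fit and no covariate, and p-values were adjusted with Benjamini-Hochberg over the kept probe sets at a threshold of 0.05. Changes are knockout minus wild type on that log2 scale, which understates the change of dim probe sets. Standard errors are those of the fit, and SDs are over the 3 arrays of a group. A second, descriptive count took probe sets at an unadjusted p under 0.01 with at least 1.5-fold change. Of 38 gene lists, the 30 with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, each gene by its brightest kept probe set, with Benjamini-Hochberg over the 30 lists; camera with an estimated correlation and fry were the alternatives. Each member was also adjusted over the list alone. Neighbours of Chga were compared with other genes by a two-sided Fisher's exact test over the 100 nearest measured genes on each side.

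The named genes were Chga; then, among genes past the adjusted threshold whose groups did not overlap, the 12 with the largest rise and the 12 with the largest fall, each by its probe set with the smallest p; then a set of key genes and up to 4 members of each list. Some of the key genes are not reported here. This rule, the lists, the tests and the alternatives were fixed before the data were examined. Chosen after seeing the data were a pseudocount 16 times as large, the match of older symbols to list members, and the background reference, the 95th percentile on each array of 27 dim Bacillus subtilis control probe sets. The alternatives were pseudocounts of 1, 64 and 16 times the main one, quantile normalization, median centring, no filter and the upper 40% by mean, eBayes without the trend, array weights, the replicate number as a block, the mean of all probe sets of a gene, other windows around Chga, and each array left out in turn.

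The procedure was tested on simulated data: in 5 runs of 3 against 3 arrays over 13576 probe sets, 51.2% of 100 probe sets changed 2-fold and 83% of 100 changed 4-fold were called, 3.17% of the calls were false, the shifted list was called in 5 of 5 runs, and 2 of 145 unshifted lists were called. The simulated probe sets varied independently of one another. In the data the estimated correlation within a list was 0.153 for lipogenesis and 0.557 for hepatocyte markers. The simulation therefore does not show how often unshifted lists of correlated genes are called. The number of arrays limits the precision. A comparison of a single value between 3 and 3 arrays has a smallest exact permutation p of 0.1, so single values are given with the fitted model only.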

Results

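Gene expression was measured in the liver of mice lacking chromogranin A (Chga), a secretory granule protein and prohormone of neuroendocrine cells, and of wild-type mice, with 3 arrays in each group. Array signals correlated between 0.964 and 0.974 within groups and between 0.960 and 0.967 across groups (Pearson's r across probe sets on the log2 scale, which are not independent), and 0 pairs were identical. Pairs of knockout arrays lay between 0.964 and 0.967, within the range across groups, and wild-type pairs between 0.970 and 0.974. The first principal component held 27.0% of the variance and separated the groups. The share of probe sets above the background reference ran from 64.4% in knockout replicate 2 to 76.9% in wild-type replicate 3. The ratio of 5′ to 3′ signal of the GAPDH controls, a sign of RNA quality, lay between 1.23 and 1.29, and that of the actin controls between 0.351 and 0.366.

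Chga itself was dim. Its only probe set read 61.5, 44.5 and 231 in the knockout arrays and 167, 185 and 42.5 in the wild-type arrays, a log2 change of -0.30 ± 0.75 (SE, n = 3 per group), with its mean at the 17.9th percentile of all probe sets. It was removed by the filter on dim probe sets, and at this level it does not check the group labels.

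The comparison of knockout with wild-type liver asks which transcripts differ when Chga is absent. Cyp17a1, a steroid hydroxylase and lyase, was higher in knockout liver (log2 change 3.84 ± 0.61 SE, n = 3 per group, adjusted p = 0.0292), at 2402 ± 1411 (SD) against 171 ± 166 in wild type, where 1 of 3 arrays was above background. The size of this change is loosely set, at 4.52 without wild-type replicate 2 and 2.54 with a pseudocount 16 times as large, and the call was lost with no filter on dim probe sets (adjusted p = 0.0513) or without the intensity trend. Fasn, the fatty acid synthase, rose 2.98-fold (1.58 ± 0.20, adjusted p = 0.00697), and Mid1ip1, which activates acetyl-CoA carboxylase, rose by 0.95 ± 0.16 (adjusted p = 0.0413). The cytochrome P450 genes Cyp2c38 (1.72 ± 0.13) and Cyp2c39 (1.69 ± 0.20), the glutathione transferase Gstt3 (1.24 ± 0.12) and the carboxylesterase Ces1d (2.48 ± 0.36) also rose. A further cytochrome P450 gene, Cyp3a13, fell (-1.62 ± 0.15). Rad51b, a recombination protein, fell (-3.12 ± 0.29, adjusted p = 0.000825), with 1 of 3 knockout arrays above background and a change of -2.25 with the larger pseudocount. The acute phase protein gene Apcs fell by 1.42 ± 0.12 on the log2 scale, from 48520 ± 6870 to 18013 ± 1744 (SD, adjusted p = 0.000746).

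The other genes among the 12 largest rises were Gng4, a G protein subunit (2.34 ± 0.29), Akirin1, a nuclear protein (1.36 ± 0.18), Tsc22d1, a transcriptional regulator (1.20 ± 0.13), Atm, a kinase of the DNA damage response (1.15 ± 0.19), and Dstn, an actin-depolymerising protein (0.86 ± 0.15). Among the 12 largest falls were the metallothionein gene Mt2 (-2.29 ± 0.37), the cytochrome P450 gene Cyp3a13 (-1.62 ± 0.15), the immediate-early transcription factor Egr1 (-1.47 ± 0.23), the cell adhesion gene Cdh1 (-1.01 ± 0.13), the RNA polymerase subunit gene Polr1c (-1.79 ± 0.20), and the transcripts 1700001C19Rik (-2.30 ± 0.31) and 4833420G17Rik (-2.30 ± 0.26). Their adjusted p-values lay between 0.000746 and 0.0457, and by the rule that chose them the groups of the 24 genes do not overlap, as chance gives for 10% of genes. Gng4 was above background in 2 of 3 wild-type arrays and 4833420G17Rik in 2 of 3 knockout arrays. For Ces1d and Polr1c the other kept probe sets did not follow the called one, with medians of 0.25 and 0.18. The other kept probe set of Akirin1 was at 0.50 and those of 4833420G17Rik at -1.20 and -1.16, none past the threshold. For Tsc22d1, 2 of the 3 others passed and the last was at 0.098. Ces1d, Cyp2c38 and Cyp2c39 belong to families of near-identical genes, so their probe sets are uncertain as to the member measured.

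Major histocompatibility genes were among the lower transcripts. The class I genes H2-Bl (-2.85 ± 0.26) and H2-K1 (-2.11 ± 0.20) and the class II gene H2-Aa (-2.03 ± 0.26) fell, with adjusted p-values of 0.000746, 0.000818 and 0.00697. Of 30 kept probe sets that carry an H2 gene name, 8 passed and all 8 were lower in knockout, 4 of them annotated to several genes. Probe sets of the same gene did not move together: those of H2-K1 ranged from -2.11 to 0.46 and those of H2-Aa from -2.03 to 0.026, and the 6 probe sets of H2-D1, from -0.93 to 0.53, did not pass. The members share sequence, so which gene each probe set measured is uncertain. Markers of Kupffer cells and macrophages, cells that express H2-Aa, had a mean of -0.32 without passing as a set (adjusted p = 0.0537).

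**Figure D1:**
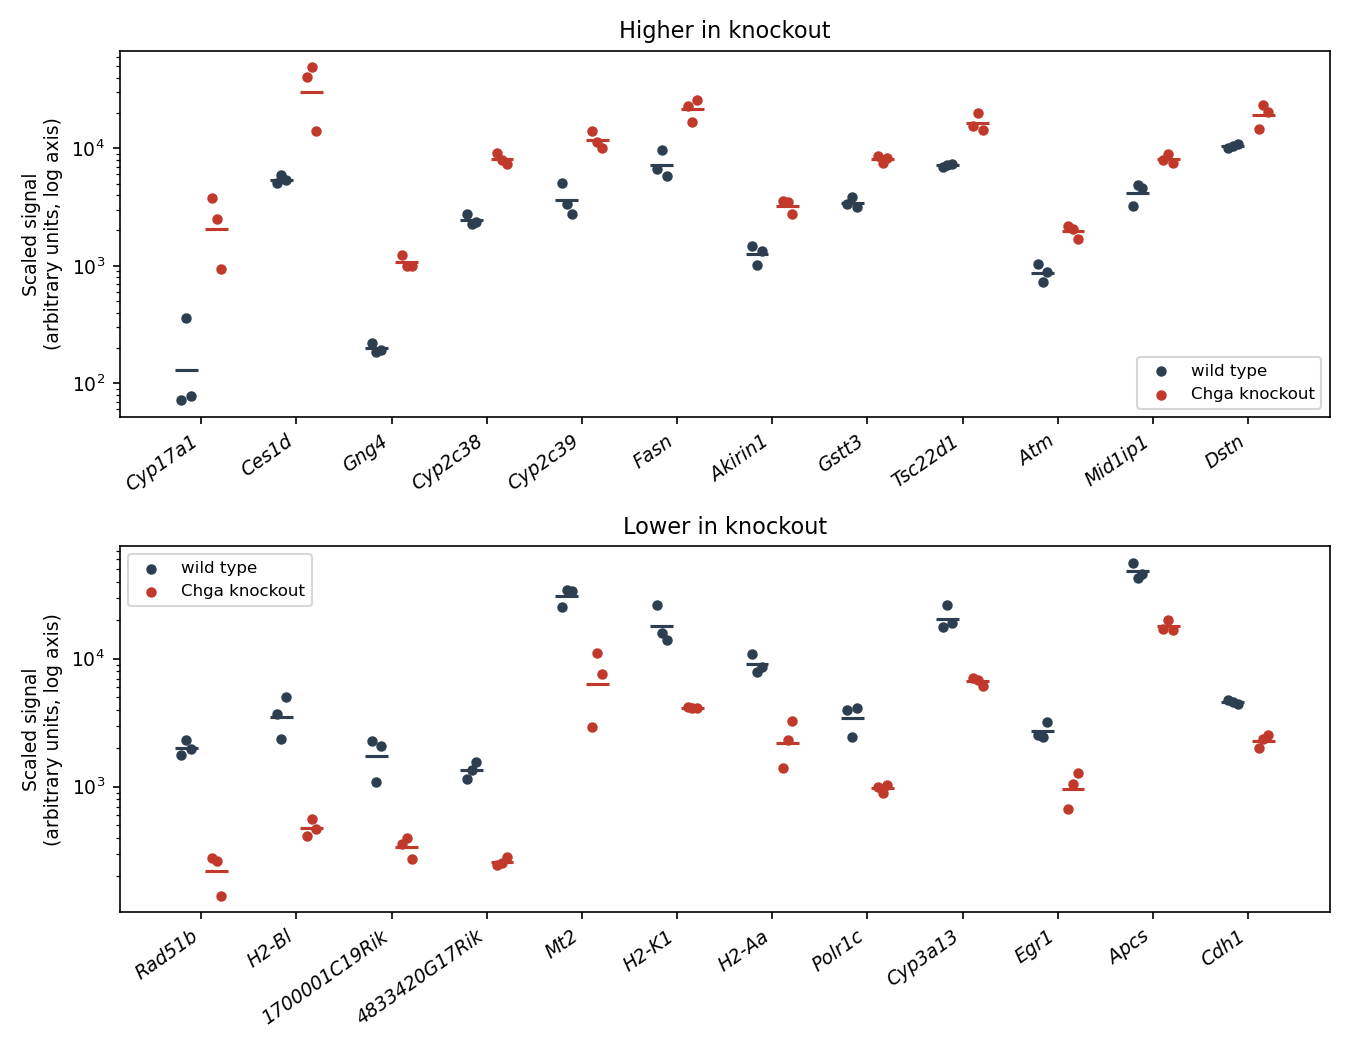
Scaled signal (arbitrary units, log axis) of the 12 genes with the largest rise and the 12 with the largest fall, with 1 point per array and a bar at the geometric mean of each group. For each gene the 3 knockout arrays lie apart from the 3 wild-type arrays, as for Fasn, which rose by 1.58 on the log2 scale.

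**Figure D2:**
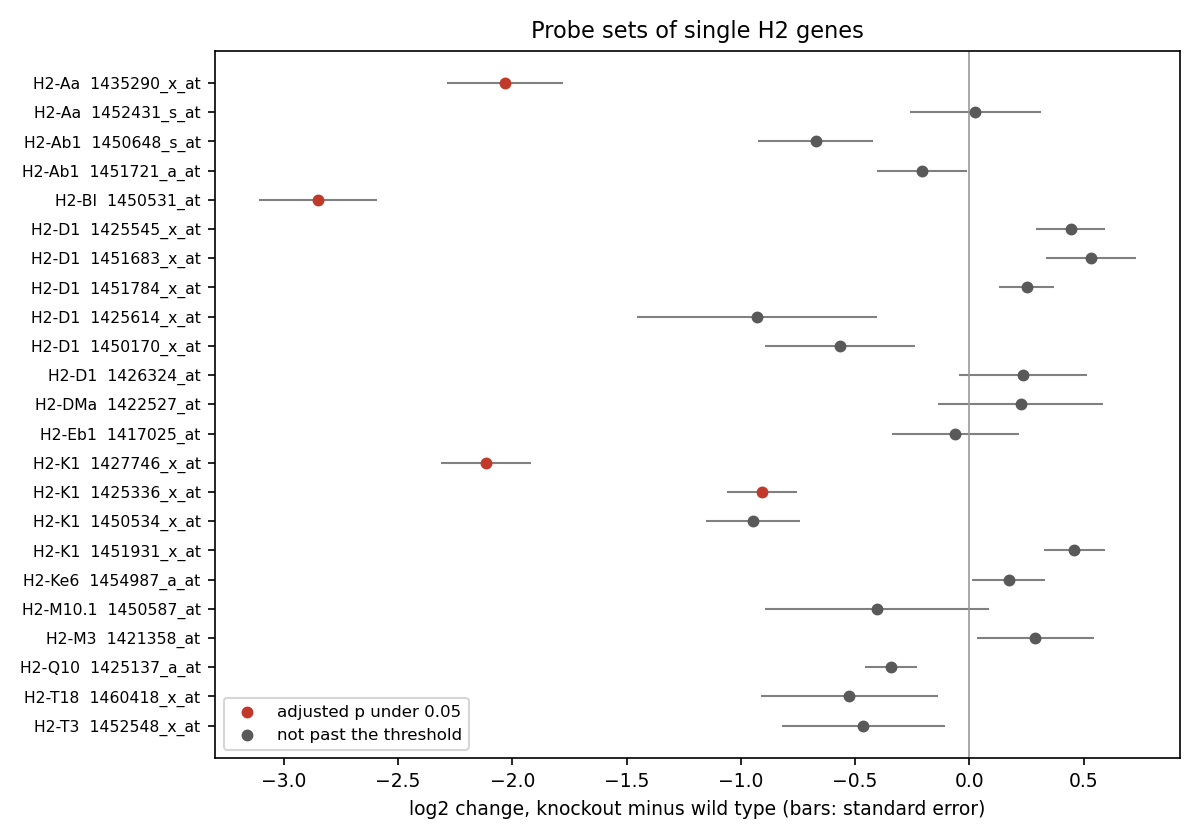
Log2 change (knockout minus wild type) of each kept probe set annotated to a single H2 gene, with bars of 1 standard error and the probe sets past the adjusted threshold in red. The probe sets of H2-K1 spread from -2.11 to 0.46.

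In all, 51 of 13576 probe sets passed with limma and Benjamini-Hochberg, 26 higher and 25 lower in knockout, standing for 20 and 19 single genes, with 7 probe sets of several genes and 1 unnamed. At an unadjusted p under 0.05 there were 1353 probe sets, where 678.8 would be expected by chance; 266 reached an unadjusted p under 0.01 with 1.5-fold change, 130 higher and 136 lower. The count fell to 23 without wild-type replicate 1 and to 21 without wild-type replicate 3, where Cyp17a1, Ces1d, Atm, Mid1ip1, Dstn, 1700001C19Rik, Mt2, Egr1 and Cdh1 no longer passed, while 15 of the 24 genes passed with each array left out in turn. With no filter on dim probe sets, Cyp17a1, Atm, Mid1ip1 and Dstn did not pass. The count was 7 without the intensity trend, and median centring gave 44 higher and 28 lower.

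Genes of fatty acid synthesis were higher in knockout liver. Of 18 measured members, 15 were higher, with a mean log2 change of 0.48 (1.39-fold) and an adjusted p of 5.85e-09 (adjusted p = 0.358 with an estimated correlation). Fasn and Acly, which makes cytosolic acetyl-CoA, passed over all genes (2 members), and 7 rose adjusted over the list alone, adding Me1, a source of NADPH (0.71 ± 0.14), Gpam, which starts glycerolipid synthesis (0.51 ± 0.11), Thrsp (0.80 ± 0.18), Acss2 (0.67 ± 0.15) and Elovl6, a fatty acid elongase (0.82 ± 0.23). Elovl6 was lost without wild-type replicate 1 or 3 (adjusted p over the list up to 0.0567). The sterol and fatty acid regulator Srebf1 (0.37 ± 0.17), the desaturase Scd1 (0.23 ± 0.09) and the carboxylase Acaca (0.42 ± 0.29) did not pass. The mean shift of the list was 0.59, 0.21 and 0.63 in the knockout arrays and -0.12, 0.18 and -0.060 in the wild-type arrays.

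Cholesterol synthesis was also higher as a set, with 16 of 19 members above wild type, a mean of 0.32 and an adjusted p of 5.98e-06 (adjusted p = 0.398 with an estimated correlation). Over all genes 0 members passed; 4 rose adjusted over the list alone, Fdps (0.92 ± 0.19), Sqle, which oxidises squalene (1.30 ± 0.30), Msmo1 (0.63 ± 0.17) and Fdft1 (0.43 ± 0.13). Without knockout replicate 3 this count was 2, Fdps and Sqle; Msmo1 was also lost without wild-type replicate 3 and Fdft1 without knockout replicate 2 or wild-type replicate 1 or 3 (adjusted p over the list up to 0.0858 and 0.177).

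The fatty acid oxidation list did not pass as a set (19 genes, adjusted p = 0.873). Over all genes 0 of its members passed and adjusted over the list alone 4 did. Cd36, a fatty acid transporter, rose by 1.42 ± 0.26, while the fasting regulator Ppara (-0.56 ± 0.13), the omega-hydroxylase Cyp4a14 (-1.01 ± 0.24) and the mitochondrial carnitine palmitoyltransferase Cpt1a (-0.31 ± 0.10) fell. Lipoprotein genes did not pass as a set either (20 genes, adjusted p = 0.759), with a median of 0.039, a mean of -0.015 and a test direction upward. Among them Abcg8, a subunit of the hepatic sterol exporter, fell by 0.77 ± 0.13 over all genes (1 member), and 5 changed adjusted over the list alone: Abcg8, its partner Abcg5 (-0.42 ± 0.13) and Lpl (-1.01 ± 0.33) fell, and Apoc3 (0.40 ± 0.08) and Pltp (1.13 ± 0.31) rose. Bile acid genes (17, adjusted p = 0.598) had 0 calls over all genes and 1 adjusted over the list alone, the export pump Abcb11, which rose by 0.48 ± 0.10. Cyp7a1, which sets the rate of bile acid synthesis, stood at 0.16 ± 0.20 and did not pass.

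Gluconeogenic genes (13, adjusted p = 0.794) had 0 calls either over all genes or adjusted over the list alone, with Pck1 at -0.15 ± 0.10, G6pc at 0.93 ± 0.39 and Fbp1 at 0.22 ± 0.08, and the coactivator Ppargc1a at -0.20 ± 0.17. Glycolysis and glycogen genes (13, adjusted p = 0.0911) had 0 calls over all genes and 2 adjusted over the list alone, in which the liver pyruvate kinase Pklr rose by 0.46 ± 0.14 and the glycogen synthase Gys2 fell by 0.40 ± 0.11. Insulin signalling genes (17, adjusted p = 0.315) had 0 calls on either count. Irs1 was at -0.12 ± 0.21, Irs2 at 0.062 ± 0.45, Foxo1 at 0.057 ± 0.15 and Igfbp1, a target repressed by insulin, at -1.60 ± 0.53. Insr was dim and was removed by the filter.

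Xenobiotic metabolism did not pass as a set (20 genes, adjusted p = 0.0714). Cyp3a13 alone passed over all genes (1 member); adjusted over the list alone 5 did, with Fmo5 (0.41 ± 0.09), Aldh1a1 (0.43 ± 0.09) and Fmo1 (0.41 ± 0.12) higher and Cyp3a13 and Cyp2b10 (-0.78 ± 0.21) lower. The oxidative stress list (15, adjusted p = 0.452) had 0 calls on either count. Genes known for higher expression in female than male liver were higher in these males as a set (5 of 7 genes higher, mean 0.95, median 0.37, adjusted p = 0.0487; adjusted p = 0.532 with an estimated correlation). Cyp17a1 was the only member to pass, over all genes (1) and adjusted over the list alone (1). Hao2 was at 2.08 ± 0.72, with overlapping groups and 2 of 3 wild-type arrays above background. Without Cyp17a1 the mean of the other 6 genes was 0.47, much of it from Hao2. Only these 7 of the 18 listed genes were measured. The filter on the mean of all 6 arrays can keep a gene dim in wild type because the knockout arrays are higher. That can favour an upward direction. With no filter on dim probe sets the set did not pass (camera, adjusted p = 0.246). The set was lost without knockout replicate 1 or 2 or wild-type replicate 1 or 3, at adjusted p-values of 0.163, 0.172, 0.0931 and 0.159. The list of male-biased genes did not pass (15, adjusted p = 0.873), with 0 calls over all genes and 3 adjusted over the list alone, Hsd3b5 (-0.69 ± 0.15) and the transporter Slco1a1 (-0.58 ± 0.18) lower and Nat8f5 (0.89 ± 0.22) higher.

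Glucocorticoid targets (16, adjusted p = 0.598) did not pass as a set. Mt2 passed over all genes (1 member) and 5 passed adjusted over the list alone, with Mt2, its sister metallothionein Mt1 (-1.74 ± 0.50), Klf9 (-0.48 ± 0.12) and Igfbp1 lower and the phosphatase Dusp1 (1.47 ± 0.30) higher. Fkbp5 was at 0.44 ± 0.24. Adrenergic and cAMP genes (13, adjusted p = 0.915), with Adra1b at 0.26 ± 0.24, had 0 calls on either count, and their mean of -0.016 and test direction, upward, differed in sign. Acute phase genes (24, adjusted p = 0.873) had 1 call over all genes, Apcs, and 2 adjusted over the list alone, Apcs and Stat3 (-0.44 ± 0.11), with a median of 0.020 and a mean of -0.011; Saa1 was at 0.49 ± 0.34. Interferon-induced genes were lower as a set (16 genes, 4 higher, mean -0.29, adjusted p = 0.0185; adjusted p = 0.358 with an estimated correlation) with 0 members called over all genes or adjusted over the list alone, Ifit3 being at -0.55 ± 0.20 and Bst2 at -0.49 ± 0.16. This set was lost without knockout replicate 1 (adjusted p = 0.0735) or wild-type replicate 2 (0.0975). The mean of the Kupffer cell and macrophage markers was close to that of the interferon set, at -0.32 (adjusted p = 0.0537). The medians were -0.23 for the macrophage markers and -0.24 for the interferon set. The means include Cd68 (-1.40 ± 0.67) and Ifi27l2a (-1.47 ± 0.62), each above background in 2 of 3 knockout arrays.

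Heat shock genes were higher as a set (11 genes, 9 higher, mean 0.29, adjusted p = 0.00231; adjusted p = 0.413 with an estimated correlation), though not without knockout replicate 1 (adjusted p = 0.0782). The constitutive chaperone Hspa8 rose by 0.46 ± 0.08 over all genes (1 member), and adjusted over the list alone Hspa1b, a stress-induced chaperone, rose too (1.22 ± 0.36), making 2, a count that ran from 1 to 6 with 1 array left out, Hspa1b holding in 2 of 6 cases. The unfolded protein response list (22, adjusted p = 0.452) had 0 calls over all genes and 2 adjusted over the list alone, Hspa5, the chaperone of the endoplasmic reticulum (0.52 ± 0.10), higher and Herpud1 (-0.47 ± 0.13) lower. Of the clock lists, the evening arm (11, mean -0.26, adjusted p = 0.0715) had 0 calls on either count, with Per1 at -1.17 ± 0.45 and Dbp at -0.35 ± 0.10.

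Urea cycle and amino acid genes were higher as a set by a small margin (19 genes, mean 0.091, adjusted p = 0.0185; adjusted p = 0.358 with an estimated correlation; 0.568 after quantile normalization), with 0 calls over all genes and 1 adjusted over the list alone, Asl (0.39 ± 0.08), which was lost without knockout replicate 3 or wild-type replicate 3 (up to 0.0609). Hepatocyte markers such as Alb (0.19 ± 0.09) were higher as a set (12 genes, mean 0.12, adjusted p = 0.0102; adjusted p = 0.567 with an estimated correlation), with 0 calls on either count and up to 6 adjusted over the list alone with 1 array left out; after quantile normalization the direction turned downward (adjusted p = 0.413), and the call was lost without knockout replicate 2 (0.148) or wild-type replicate 2 (0.0975). Oxidative phosphorylation (35, adjusted p = 0.120), pericentral (11, 0.136), periportal (9, 0.799) and cell cycle genes (5, 0.915) had 0 calls on either count. The periportal mean of -0.016 and the cell cycle mean of 0.049 differed in sign from the test, and the cell cycle median was -0.017. Ribosomal protein genes (21, adjusted p = 0.0537) had 0 calls over all genes and 1 adjusted over the list alone, Rps27 (1.38 ± 0.28).

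Markers of other cell types did not pass as sets. Kupffer cell and macrophage markers had a mean of -0.32 (10 genes, 1 higher, adjusted p = 0.0537), stellate cell and matrix genes -0.20 (11 genes, 2 higher, adjusted p = 0.0537) and endothelial markers 0.0041, with a median of -0.034 (13 genes, adjusted p = 0.873), each with 0 calls on either count. Pancreatic genes (5, adjusted p = 0.759, mean 0.048, median -0.20) had 0 calls over all genes and 1 adjusted over the list alone, the elastase Cela1 (-0.58 ± 0.17). Lists with too few measured genes were not tested as sets. They were the granin family (1 gene, Pam, -0.27 ± 0.36), the morning arm of the clock (4 genes, mean 0.090), lymphocyte and neutrophil markers (3 genes each), adipose genes (2), the erythroid gene Alas2 (-0.026 ± 0.14), the Y-linked genes (3), and cholangiocyte markers (0 measured). Of these only Car3, an adipose list gene that liver also expresses, passed adjusted over the list alone (0.22 ± 0.08), with 0 calls over all genes.

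**Figure D3:**
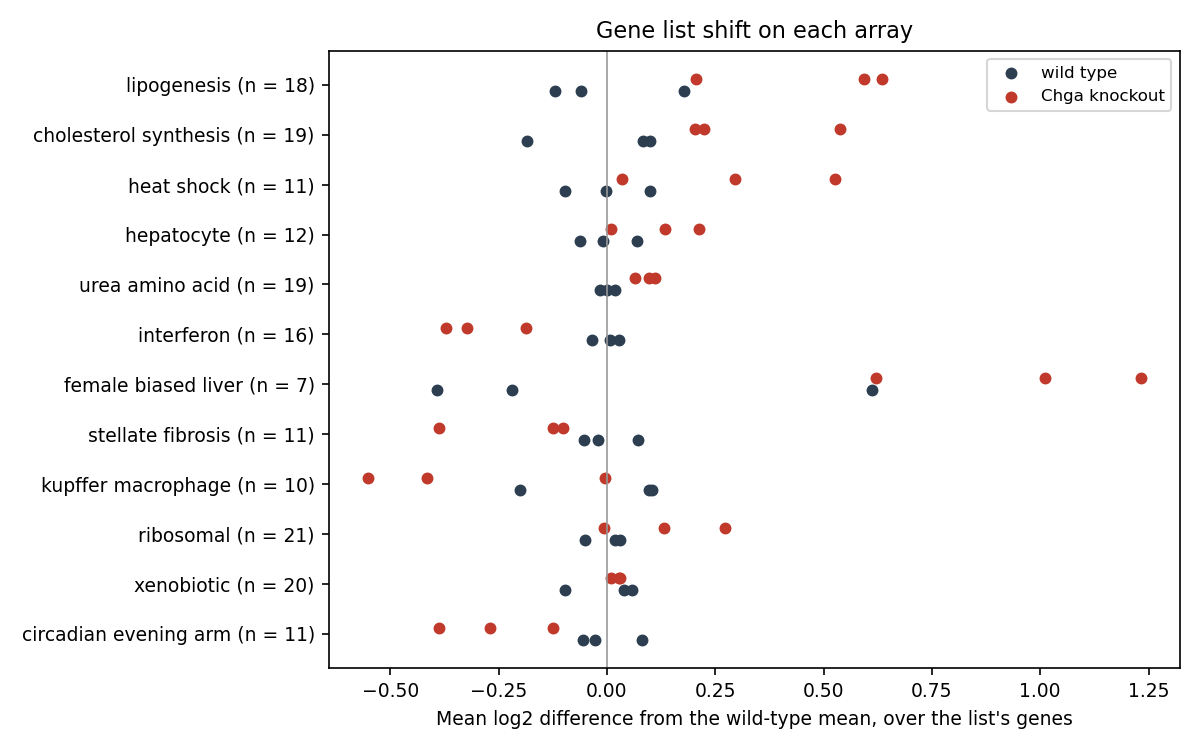
Mean log2 difference of each array from the wild-type mean over the genes of 12 lists, with 1 point per array and the number of measured genes in parentheses. For lipogenesis the knockout arrays lie at 0.59, 0.21 and 0.63 and the wild-type arrays at -0.12, 0.18 and -0.060.

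With the preset correlation, 7 of 30 lists passed, 6 higher and 1 lower; with an estimated correlation 0 passed, and by fry 0. The highest count in any other division of the 6 arrays into groups of 3 was 6 lists. Of 47 member calls adjusted over the list alone, 24 held with each array left out in turn: Fasn, Acly, Me1, Gpam, Thrsp and Acss2; Fdps and Sqle; Ppara, Cyp4a14 and Cd36; Apoc3 and Abcg8; Cyp3a13, Aldh1a1 and Fmo5; Cyp17a1; Dusp1, Mt2 and Klf9; Apcs; Hspa5; Hspa8; and Rps27. Leaving out 1 array also added calls, those higher reaching 7 from 3 for xenobiotic metabolism, 6 from 4 for cholesterol synthesis, 3 from 1 for bile acid, male-biased and female-biased genes and 2 from 0 for oxidative stress, and those lower 2 from 0 for oxidative stress, interferon and evening clock genes.

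Genes near Chga on chromosome 12 were compared with all others, since a targeted allele carries flanking sequence of the embryonic stem cell strain. Among 100 measured genes before Chga and the 58 after it, 10 of 244 probe sets (4.10%) had an unadjusted p under 0.01, against 397 of 12220 elsewhere (3.25%), an odds ratio of 1.27 (95% interval 0.598 to 2.41, Fisher's exact test, p = 0.463). Rad51b, 71 measured genes before Chga, was the 1 gene in the window past the adjusted threshold. The odds ratio was 0.667 without wild-type replicate 3.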

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

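Of the settings below, only a pseudocount 16 times as large was chosen after seeing the data. In every setting run, the 51 called probe sets that were still tested kept their sign. This tests little. Where groups do not overlap, as for the 24 genes with the largest changes, leaving out an array or changing the pseudocount cannot turn the sign. The count of calls was 85 with that pseudocount (41 higher, 44 lower), 72 with median centring (44 higher, 28 lower), 82 with array weights (38 and 44), 42 with no filter (17 and 25), 70 with the upper 40% of probe sets, 60 after quantile normalization and 7 without the intensity trend (2 and 5, all 7 among the main 51). With the trend left out Gng4, Cyp2c38, Rad51b, H2-Bl and 4833420G17Rik passed among the 24 genes with the largest changes. Leaving out 1 array gave 21 to 57 calls, 8 to 25 of them higher and 11 to 36 lower; the higher calls numbered 16 without knockout replicate 2, 12 without wild-type replicate 1 and 8 without wild-type replicate 3, the lower calls 11 and 13 without those wild-type arrays, which leave fewer samples. Among the named genes, Cyp17a1, Atm and Mid1ip1 were lost without knockout replicate 1, these with Dstn and Egr1 without knockout replicate 2, Mid1ip1 and Dstn without knockout replicate 3, and Atm, Dstn, Mt2 and Egr1 without wild-type replicate 2; Cyp17a1, Atm, Mid1ip1 and Dstn also did not pass with no filter.

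Same-numbered arrays did not deviate together, with correlations of deviations from the group means of -0.059, -0.060 and -0.065. Of the arrays, 0 correlated best with their own number. The values thus gave no sign of pairing by number. They cannot show how mice or arrays were matched, which the labels do not give. With the replicate number as a block 27 probe sets were called, 12 higher and 15 lower, 25 of them among the 51, Atm, Mid1ip1, Dstn and Cdh1 not among them, and 3 lists were called lower in place of 1.

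Lists called higher numbered 3 after quantile normalization, 3 with no filter, 3 without the trend, and 0 with an estimated correlation or fry, against 6 in the main setting; lists called lower numbered 3 with median centring, 0 with an estimated correlation or fry, and 0 to 3 with 1 array left out (2 without knockout replicate 2, 3 without knockout replicate 3, 0 without wild-type replicate 2, 2 without wild-type replicate 3). With fry the adjusted p was 0.120 for lipogenesis, 0.382 for cholesterol synthesis, 0.382 for heat shock, 0.478 for hepatocyte markers, 0.0940 for urea and amino acid genes, 0.0577 for interferon genes and 0.532 for female-biased genes; with an estimated correlation it was 0.358, 0.398, 0.413, 0.567, 0.358, 0.358 and 0.532. Lipogenesis and cholesterol synthesis passed in each of the other settings. Female-biased genes missed the threshold with a pseudocount of 1 (0.0520), quantile normalization (0.0629), median centring (0.0548), no filter (0.246) and no trend (0.104), and ranged from 0.00110 to 0.172 with 1 array left out. Interferon genes missed it with the upper 40% (0.103) and ranged from 0.0136 to 0.0975, heat shock genes from 5.45e-06 to 0.0782. Urea and amino acid genes missed it after quantile normalization (0.568), with no filter (0.0655) and without the trend (0.104). Hepatocyte markers turned downward after quantile normalization (0.413), missed the threshold with no filter (0.0505) and without the trend (0.0911), and ranged from 1.67e-05 to 0.148. The odds ratio of the neighbours of Chga was 0.987 with 50 genes a side and 0.984 with no filter, and ran from 0.667 to 1.62 with 1 array left out; with 50 genes fewer genes are tested, and for the other changes the cause was not tested. Of the results for single genes and for lists not called in the main setting, 2774 values stayed on their side, 42 newly passed, 82 no longer passed and 66 moved. Near background, signal limits what can be read: up to 321.8 units on knockout replicate 2 lie within the range of the control probe sets.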

Other observations

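Chosen only after the result was seen were the tests of probe sequence and of a linked block for the H2 genes, of feeding, time of day and hepatocyte share for the lipogenic genes, and of placement for chromosome 9. For the class I programme and the divisions of the samples, the bounds were written before the results of those tests were seen. The linked-block and feeding tests replaced earlier versions whose results had been seen, and both versions are given.

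Further genes passed the adjusted threshold outside the rule for named genes and were picked out after their values were seen. Leap2, a liver antimicrobial peptide that also blocks the ghrelin receptor (0.53), the glutathione transferase Gsta3 (0.53), Pebp1, a kinase inhibitor (0.65), the cargo receptor Lman1 (0.62), the tubulin Tubb4b (0.85) and Hopx (0.66) rose. Fdx1, the electron donor of mitochondrial steroid hydroxylases (-0.48), the glycogen-binding protein Stbd1 (-0.64), the phosphodiesterase Gpcpd1 (-0.98), the kinase Map3k12 (-0.82), Rcl1 (-0.55) and Ralgps2 (-0.95) fell. Each value is a log2 change from 3 against 3 arrays with an adjusted p between 0.0195 and 0.0435 (limma, Benjamini-Hochberg).

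Lower H2 probe sets are the first pattern. A lowered class I programme is argued against for the genes listed, as a set. The 10 antigen-processing genes not named H2 had a median log2 change of 0.034, with B2m at 0.049 ± 0.094 (SE). However, Tap1 (-0.42 ± 0.20) and Psmb10 (-0.36 ± 0.13), neither past the adjusted threshold, were lower, and the interferon list was lower as a set (mean -0.29). Of the 10, Tap1, Tap2, Tapbp, Psmb8 and Psmb9 are encoded within the H2 complex, so they are not independent of differences there. Different H2 haplotypes that bind the probes unequally stay open: the 4 probe sets of H2-K1 differed by up to 2.57, which 0 of 226 other genes with 4 kept probe sets reached, but H2-K1 was singled out after its range was seen, and the range does not tell haplotype from other faults of a probe. A linked block of another strain around H2 may contribute. It was first tested by probe sets, which met the bound set for it. Of 300 near H2-K1, 20 had an unadjusted p under 0.01 (odds ratio 2.20, interval 1.31 to 3.52, Fisher's exact test, p = 0.00228). Fisher's exact test gave 1.73 with 50 genes a side (interval 0.727 to 3.54, p = 0.151) and 1.97 with 200 (interval 1.33 to 2.84, p = 0.000602). Several of the 20 were repeats of Glo1, Crebrf and Ergic1. With 1 probe set per gene the window of 200 genes held 12, which also left out Polr1c, Ppp1r11, Mmut and Abcf1. Polr1c had passed the adjusted threshold, though its other kept probe set, at 0.18, did not follow. Across the genome 10.6% of windows of 200 genes and 22.3% of windows of 100 were as dense, which leaves the block open. A lower share of macrophages, whose markers had a mean of -0.32 (shifts of -0.55, -0.41 and -0.0035 on the knockout arrays, 0.10, 0.097 and -0.20 on the wild type) without passing as a set (adjusted p = 0.0537), was not tested as a cause, nor was an effect of Chga itself, and the labels name no strain for the wild type. On knockout replicate 3, with the macrophage shift of -0.0035, the called probe set of H2-Aa read 3279, against 7946 to 10929 in wild type. Other class II genes were mixed, with H2-Eb1 at -0.063 ± 0.28, H2-DMa at 0.22 ± 0.36 and the probe sets of H2-Ab1 at -0.67 ± 0.25 and -0.21 ± 0.20. None of these passed the adjusted threshold.

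Higher lipogenic genes are the second pattern. A higher share of hepatocytes stays open as part of the cause: the lipogenic mean exceeded that of the hepatocyte markers by 0.36 ± 0.22 (SE over arrays), but the difference on single arrays overlapped between the groups, at 0.58, -0.0078 and 0.50 on the knockout and -0.11, 0.24 and -0.13 on the wild type. The markers' mean shift rose with the highest signal of each array. It was -0.062 on wild-type replicate 2, where that signal was 208581, and 0.21 on knockout replicate 2, at 269124. Their set also turned downward after quantile normalization. The markers are themselves among the brightest probe sets, with Serpina1c at 194404 to 237339 on the knockout arrays. Quantile normalization evens out the top of each array. Neither observation can therefore tell a difference in signal range from one in cell share, and how well the markers measure that share is not known. Feeding state could contribute: a list of 21 fasting-induced genes was lower (median -0.19, camera p = 0.000394, and p = 0.0290 with an estimated correlation), but the values of some members had been seen when it was written, and the 13 others alone gave a median of -0.080 (p = 0.935). Time of day stays open too, with the evening arm of the clock below the morning arm by a difference of -0.35, between the bounds set for it. The knockout itself remains a further explanation, untested.

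Changed genes gathered on chromosome 9 are the third pattern, found by scanning all chromosomes in windows of 3 sizes on the same data. In the densest window of 100 measured genes, from Rpusd4 to Cox5a, 15 genes had an unadjusted p under 0.01, where 3.38 were expected, among them Nnmt (1.19 ± 0.24 SE), Sorl1 (-2.24 ± 0.50), Rcn2 (-1.32 ± 0.26), Apoc3 (0.40 ± 0.08), and Hspa8, Fdx1 and Atm, the 3 past the adjusted threshold. Of the 15, 10 were higher and 5 lower in knockout. Placement by chance is argued against, as a window as dense arose in a share of 0.00070 of 10000 shuffles (0.0349 for 50 genes and 0.0103 for 200), though neighbouring genes are not independent. A segment of another strain may lie there, which was not tested.

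The 51 called probe sets and the 7 called lists were set against all 10 divisions of the 6 arrays into groups of 3. In each case the real division was the only 1 as large, the highest others being 2 probe sets and 6 lists, and with 10 divisions the share cannot get under 0.05.

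A list of 11 immediate-early genes did not move as a set (camera p = 0.810 with the preset correlation), with Egr1 lower and Dusp1 (1.47 ± 0.30) and Fos (0.79 ± 0.32) not past the threshold over all genes. Over 13 called genes outside H2 with further kept probe sets, the others showed a median of 51.2% of the called change, and under 25% for 2 genes, Polr1c and Ces1d; this was looked at as a sign of probe-level faults and set aside after its result was seen.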
